A study of Mus musculus with 6 samples.

How the data were processed

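The samples were 6 total RNA libraries of the mouse melanoma line YUMMER1.7, 3 with a control guide and 3 with a Kdm5b guide, prepared with a stranded total RNA kit. Per the labels, the submitters used the mm10 genome, CASAVA, STAR, featureCounts from Subread and DESeq2, and the versions are not given in the sources used here. How reads that map to several loci were counted, the strand setting and the overlap rule are not given in the sources used here. The deposited count table holds raw counts, as whole numbers, for 5147736 RepeatMasker loci with 1554 repeat names. The authors' deposited table gives a log2 fold change and an adjusted p value (p_value unit) for 1000 loci, and the method of adjustment is not given in the sources used here. Among values from 2 to 21 in the deposited counts, 73.1% to 78.1% were even in each library, so single counts are not independent molecules. A table of gene counts was not used here.

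Total counts per library ranged from 4133181 to 12806810. Each locus was placed in exons, introns or outside genes of the GENCODE M21 annotation of GRCm38, which has 55536 genes, with bedtools 2.31.1. Subfamily values were sums over all loci with a RepeatMasker name. Gene values were sums over repeat loci that lie wholly inside exactly 1 gene body, so a gene with no repeat of its own was not measured. The repeat classes are not in the file, and shares were therefore computed over lists of names.

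Counts were tested in R 4.3.3 with the edgeR 4.0.16 quasi-likelihood test, TMM scaling within each table and filterByExpr with a minimum count of 10, between the groups with no covariate, and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. This left 36725 loci, 1155 subfamilies and 11747 genes. At an unadjusted p under 0.05 there were 16457, 524 and 5537. Repeat and gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the lists. Subfamily enrichment used one-sided Fisher's exact tests for subfamilies with at least 10 tested loci, against all tested loci. Shares used exact two-sided permutation tests. Folds against a group with 0 counts used a floor of 3 counts over the group, and groups with 1 to 3 counts were given a ratio with a 95% counting interval.

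The lists, tests and first set of alternatives were fixed before the data were examined. Items were named by a rule: adjusted p under 0.05, every Kdm5b guide library on the same side of every control library, and a mean count of at least 50 for subfamilies and genes or 20 for loci. From these, the 15 subfamilies and the 10 loci and 10 genes with the largest rise and the largest fall were taken, with list members past the threshold and Kdm5b itself. The repeat lists were VL30, IAP, MERVL, ETn and MusD, MMERVK10C, MuLV, GLN, RLTR44 and RLTR45, MaLR, young and older LINE-1, SINE B1, SINE B2 to B4, satellites and small RNA repeats. The gene lists were interferon response, antigen presentation, nucleic acid sensing, repeat silencing, the KDM5 family, melanocyte lineage, dedifferentiated melanoma, cell cycle, and markers of fibroblasts, myeloid and lymphoid cells, and keratinocytes and endothelium. Lists of heat shock, NRF2 target, sterol and fatty acid synthesis, p53 target, NF-kB chemokine and extracellular matrix genes were added after the results were seen.

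Alternatives were DESeq2 size factors, library totals, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, each library left out in turn, other filters on low counts, other scaling tables, and sums limited to loci outside exons, outside genes or in introns. Thinning to equal depth, halved counts, scaling within each genomic context, exonic sums, the repeat lists on loci outside genes, and leaving out libraries for the context and enrichment tests were added after the data were seen. The pipeline was tested on simulated data with 100 features changed at each fold size, among 36725 loci, 1155 subfamilies or 11747 genes. Fewer features were changed than were called in the data, which makes the adjusted threshold stricter in the simulation. Of features changed 2-fold, 0% of loci, 72% of subfamilies and 10% of genes were found, and of those changed 4-fold, 12%, 97% and 71%. Of unchanged features, 2 of 33664 loci, 7 of 947 subfamilies and 7 of 11290 genes were called, and 0 of 20 unchanged sets.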

Results

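Total RNA was sequenced from YUMMER1.7, a mouse melanoma cell line driven by mutant Braf with loss of Pten and Cdkn2 and mutagenised with ultraviolet light, grown in culture. The series holds 6 libraries in 2 groups of 3: cells with a control guide and cells with a guide against Kdm5b, which encodes a histone H3 lysine 4 demethylase. The labels name 3 Kdm5b guide samples by number and do not say whether these are different guides, clones or cultures, so each p below measures the spread between these libraries only. The deposited values are raw counts at 5147736 RepeatMasker loci of the mm10 genome, of which 705623 had a count in at least 1 library. The control libraries held 12806810, 9633310 and 7476063 counts, and the Kdm5b guide libraries held 6020570, 6133797 and 4133181, so depth differed with the group. Loci with a count numbered 441144, 288974 and 309284 in the controls and 192742, 201854 and 166539 with the Kdm5b guide. Floors and counting intervals given here take each count as independent and leave out the spread between libraries. Since most small counts were even, folds given as at least a value may be too high and these intervals too narrow.

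The libraries also differed in makeup. Loci on the mitochondrial chromosome took 1.39%, 0.743% and 1.05% of counts in the controls and 0.162%, 0.178% and 0.167% with the Kdm5b guide. Control 1 stood apart from the other controls. Its intronic loci took 26.8% of counts against 19.5% and 21.9% in controls 2 and 3 and 19.3%, 18.5% and 18.1% with the Kdm5b guide. Its exonic loci took 41.9% against 53.3% and 51.8% in the other controls and 52.9%, 53.8% and 56.2% with the Kdm5b guide.

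The target gene was read from the 92 repeat loci inside its body, Kdm5b (ENSMUSG00000042207.17, chromosome 1, 134560171 to 134635285). These loci held 255, 83 and 98 counts in the controls and 28, 36 and 16 with the Kdm5b guide. Counts over the TMM-scaled total of the gene table (CPM) were 20.9 ± 5.53 (SD, n = 3) in the controls and 9.68 ± 2.06 (SD, n = 3) with the guide, a log2 fold change of -1.10 (SE 0.32, adjusted p = 0.0296, edgeR), with every guide library below every control library. Over the total of all repeat counts, with no TMM factor, the same counts gave 19.9, 8.62 and 13.1 CPM in the controls and 4.65, 5.87 and 3.87 with the guide. The exonic loci of Kdm5b held 49, 33 and 30 counts against 6, 11 and 2, a log2 fold change of -1.76 (adjusted p = 0.0190, edgeR). Its intronic loci had a log2 fold change of -0.35 (adjusted p = 0.480, edgeR). The exonic and the intronic values were each scaled within sums of their own kind, so a fall common to intronic loci is taken out. Over the total of all repeat counts the intronic loci gave 16.1, 5.19 and 9.10 CPM in the controls. With the guide they gave 3.65, 4.08 and 3.39. The Kdm5b call from all its loci was lost without control 3 (adjusted p = 0.0810), without Kdm5b guide library 1, 2 or 3 (adjusted p = 0.128, 0.0805 and 0.145), and after thinning to equal depth (adjusted p = 0.0643). With the replicate number as a block the call was lost too. The guide's target site is not given in the sources used here, and repeat counts do not show whether the protein was lost.

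The first comparison asked which retroelements changed when Kdm5b was targeted, since the series concerns retroelement expression. VL30 elements, a family of endogenous retrovirus-like elements with no full coding capacity, rose most widely: of 766 tested loci, 461 rose, 3 fell and 302 did not pass, with a median log2 fold change of 1.64. The summed VL30 counts rose from 19444 ± 7610 to 69713 ± 6810 CPM (SD, n = 3 each; log2 fold change 1.84, SE 0.26, adjusted p = 0.0026, edgeR), higher in each of the 3 guide libraries than in any control. VL30 took 2.06 ± 0.770% of all counts in the controls and 6.53 ± 0.404% with the Kdm5b guide (SD, n = 3 each). Among its names, MMVL30-int rose by 1.92 (SE 0.25, adjusted p = 0.0027), RLTR6-int by 1.92 (SE 0.18, adjusted p = 7.6e-04) and RLTR6_Mm by 1.77 (SE 0.36, adjusted p = 0.012) on the log2 scale in edgeR. VL30 loci outside annotated genes showed the same direction, with 360 of 601 risen and 0 fallen at a median of 1.69.

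For VL30 the set test with a preset correlation gave an adjusted p of 1.1e-33 (camera), and adjusted p = 0.474 with an estimated correlation. Adjusted over the list alone, 554 VL30 loci rose and 7 fell. Without control 1, 2 or 3 the risen VL30 loci numbered 739, 536 and 282, and without Kdm5b guide library 1, 2 or 3 they numbered 358, 339 and 448.

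Other endogenous retroviruses moved in both directions. MMERVK10C and its LTRs rose at 155 of 562 loci, fell at 7 and did not pass at 400, with a median log2 fold change of 1.36 and a summed change of 1.22 (SE 0.30, adjusted p = 0.019, edgeR). Within that list MMERVK10C-int rose from 877 ± 572 to 3373 ± 100 CPM (SD, n = 3 each), a call that was lost without control 3 (adjusted p = 0.064) and without Kdm5b guide library 1, 2 or 3 (adjusted p = 0.056, 0.052 and 0.053, edgeR). GLN elements, a gammaretrovirus-like family, fell at 237 of 295 loci, rose at 4 and did not pass at 54, with a median of -1.46. GLN took 13.5 ± 2.46% of counts in the controls and 5.56 ± 0.252% with the guide (SD, n = 3 each), and its summed log2 fold change was -1.10 (SE 0.16, adjusted p = 0.0027, edgeR). MaLR elements, nonautonomous LTR retrotransposons, fell at 669 of 2187 loci, rose at 133 and did not pass at 1385, with a summed change of -0.46 (SE 0.09, adjusted p = 0.0086, edgeR). Of its 26 names 8 fell and 1 rose, and much of the fall lay in MTA_Mm-int and MTA_Mm. The mean of the list went from 28529 to 20730 CPM, that of MTA_Mm-int from 8749 to 4880 and that of MTA_Mm from 5409 to 2594. These 2 names held 311 and 141 of the fallen loci.

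The set test of MMERVK10C gave adjusted p = 2.5e-18 (camera), and adjusted p = 0.474 with an estimated correlation; 155 loci rose and 7 fell when adjusted over the list alone. GLN gave adjusted p = 8.1e-23, and adjusted p = 0.474 with an estimated correlation; 5 rose and 256 fell when adjusted over the list alone. MaLR gave adjusted p = 1.4e-08, and adjusted p = 0.149 with an estimated correlation; 151 rose and 768 fell when adjusted over the list alone. Without control 1, 3 or Kdm5b guide library 1, 2 or 3, the risen MMERVK10C loci numbered 445, 36, 85, 74 and 87. Fallen GLN loci numbered 44, 35 and 38, and fallen MaLR loci 67, 65 and 91, without guide library 1, 2 and 3. Fallen MaLR loci numbered 323 without control 3 and 430 by limma-voom, and risen MaLR loci 81, 74 and 78 without guide library 1, 2 and 3.

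Intracisternal A particles (IAP), which transpose in mouse cells, rose at 626 of 3150 loci, fell at 219 and did not pass at 2305, with a median log2 fold change of 0.36. Their summed counts were 45798 ± 3820 and 50619 ± 881 CPM (SD, n = 3 each), a difference that did not pass (adjusted p = 0.306, edgeR). The IAP member IAPEY4_I-int rose by 2.00 on the log2 scale (SE 0.30, adjusted p = 0.0044, edgeR). MERVL elements, known from early embryos, rose at 63 of 883 loci, fell at 22 and did not pass at 798, and their summed counts rose by 0.55 (SE 0.13, adjusted p = 0.016, edgeR). Of 430 MERVL loci outside genes 23 rose and 3 fell, at a median of 0.44. Exons held 88.6%, 83.6% and 71.9% of the counts of the risen names MT2B, MT2B2 and MT2A. Outside genes MT2A rose by 0.78 (adjusted p = 0.0077, edgeR). There MERVL-int at 0.62, MT2B at -0.13 and MT2B2 at 0.18 did not pass (adjusted p = 0.119, 0.720 and 0.571, edgeR). ETn and MusD elements fell at 33 of 168 loci and rose at 2, with 133 that did not pass and a summed change of -0.45 (adjusted p = 0.068, edgeR). Murine leukemia virus (MuLV) elements fell at 90 of 342 loci and rose at 6, with 246 that did not pass and a summed change of -0.39 (adjusted p = 0.077, edgeR). RLTR44 and RLTR45 elements rose at 3 of 19 loci and fell at 0, with 16 that did not pass and a summed change of 0.20 (adjusted p = 0.250, edgeR). Of their 8 names 0 rose and 1 fell. That name, RLTR44E, had 126 counts in the controls and 14 with the guide (log2 fold change -2.05, adjusted p = 0.040, edgeR), a call lost in 6 of 15 other settings.

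Set tests gave adjusted p = 3.4e-05 for IAP, 7.4e-04 for MERVL, 2.8e-05 for ETn and MusD, 1.6e-09 for MuLV and 0.268 for RLTR44 and RLTR45 (camera). In the same order it gave adjusted p = 0.335, 0.569, 0.474, 0.536 and 0.536 with an estimated correlation. Adjusted over the list alone, 605 IAP loci rose and 208 fell, 26 MERVL loci rose and 4 fell, 2 ETn and MusD loci rose and 20 fell, 6 MuLV loci rose and 90 fell, and 3 RLTR44 and RLTR45 loci rose with 0 fallen. With no filter on low counts the medians turned in sign, to -0.23 over 11796 IAP loci, from 0.39 to -0.82 for MERVL and from 0.14 to -1.51 for RLTR44 and RLTR45. At 10 counts in total the last 2 medians were -0.03 and -0.62. With no filter the same median of -1.51 also held for ETn with MusD and for small RNA repeats. A value shared by unlike lists marks loci with very few counts, so the unfiltered medians show no direction of these elements. Without control 1, 3 or Kdm5b guide library 1, 2 or 3, risen IAP loci numbered 1005, 237, 298, 273 and 316, and fallen IAP loci 391, 106, 38, 21 and 18. In the same order risen MERVL loci numbered 264, 33, 34, 27 and 25, and fallen ones 32, 6, 2, 2 and 3. Without control 2, 135 IAP loci fell. The RLTR44 and RLTR45 loci numbered 5 risen and 3 fallen without control 1, and 1 risen and 0 fallen without control 3 or any single guide library. Fallen ETn and MusD loci numbered 17 and 8 without control 2 and 3 and 0 without any single guide library, and fallen MuLV loci numbered 166 without control 1 and 14, 7 and 2 without guide library 1, 2 and 3, with 6 risen in the last of these.

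As whole lists, LINE and SINE elements, the main non-LTR retrotransposons, showed no summed change that passed. By name, 3 of 24 older LINE-1 subfamilies rose and 4 fell, 1 of 6 young ones rose, and 0 SINE names passed. L1VL4 rose by 0.61 (adjusted p = 0.015) and L1_Rod had a log2 fold change of -0.94 (adjusted p = 0.0039, edgeR). Exons held 52.2% of L1_Rod counts, with 28.7% of its counts at a single exonic locus in Cp and Hps3. Outside exons L1_Rod moved to -0.18 and its call was lost (adjusted p = 0.423), while L1VL4 rose by 1.43 (adjusted p = 0.0028, edgeR). Young LINE-1 elements rose at 90 and fell at 82 of 531 loci, with 359 that did not pass and summed counts of 10083 ± 1582 and 10142 ± 745 CPM (SD, n = 3 each; adjusted p = 0.966, edgeR). Older LINE-1 elements rose at 138 and fell at 180 of 925 loci, with 607 that did not pass. The balance turned to 168 risen and 153 fallen with the subfamily scaling, and to 126 and 93 by limma-voom. SINE B1 elements rose at 613 and fell at 797 of 4806 loci, with 3396 that did not pass and a median of -0.16 that became 0.01 when the subfamily scaling was used. That scaling gave 781 risen and 672 fallen SINE B1 loci. SINE B2, B3 and B4 elements fell at 1152 of 6420 loci, rose at 284 and did not pass at 4984. Their summed counts were 151528 CPM in control 1, against 50665 and 65963 in controls 2 and 3 and 53112, 51974 and 45442 with the guide (adjusted p = 0.125, edgeR). Without control 1 the median of SINE B2, B3 and B4 loci moved from -1.46 to -0.44. Without Kdm5b guide library 1, 2 or 3, more loci rose than fell for SINE B1 (307 and 132, 283 and 122, 309 and 146) and for older LINE-1 (79 and 35, 71 and 31, 80 and 36), and young LINE-1 loci numbered 35 and 8, 38 and 10, and 47 and 15. The medians of all tested loci stayed below 0 in these fits, at -0.39, -0.41 and -0.43 for SINE B1 and -0.47, -0.52 and -0.55 for older LINE-1. Without control 3 the risen and fallen loci numbered 274 and 353 for SINE B1, 79 and 74 for older LINE-1 and 33 and 21 for young LINE-1, and limma-voom gave 599 and 381 for SINE B1. Fallen SINE B2, B3 and B4 loci numbered 3347 and 584 without control 2 and 3 and 111, 87 and 117 without Kdm5b guide library 1, 2 and 3, where 162, 151 and 173 rose. By limma-voom 305 fell.

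Satellite repeats rose at 258 of 1044 loci, fell at 33 and did not pass at 753. Outside genes 6 of 66 satellite loci rose and 6 fell, at a median of 0.23. Over all satellite loci the summed counts rose by 0.85 on the log2 scale (SE 0.10, adjusted p = 0.0013, edgeR). The satellites MMSAT4 and MurSatRep1 rose by 0.93 and 0.94, and 97.0% and 93.9% of their counts lay in exons of annotated genes. Outside genes the log2 fold change was 0.72 for MMSAT4 (adjusted p = 0.012) and 0.40 for MurSatRep1 (adjusted p = 0.110, edgeR), a call lost there. With no filter on low counts the satellite median was -0.29 in place of 0.50, and that of small RNA repeats -1.51 in place of 0.23. Loci with very few counts weigh in these unfiltered medians, which therefore show no direction. Repeats named after small structural and ribosomal RNAs rose at 22 and fell at 29 of 245 loci, with 194 that did not pass, while their summed counts rose by 0.74 on the log2 scale (SE 0.19, adjusted p = 0.023, edgeR). That rise lay in LSU-rRNA_Hsa, a large ribosomal RNA, at 106862 ± 37465 and 199533 ± 29424 CPM (SD, n = 3 each; log2 fold change 0.90, adjusted p = 0.044, edgeR), a call lost without control 3, without any single guide library, with library totals, the locus scaling or no filter, and outside exons or genes (adjusted p from 0.054 to 0.137). The rest of the list summed to 30022 ± 8601 and 28336 ± 5491 CPM (SD, n = 3 each; log2 fold change -0.08, adjusted p = 0.824, edgeR). The share of the list was 14.6 ± 3.26% in the controls and 21.4 ± 2.13% with the guide (SD, n = 3 each), and LSU-rRNA_Hsa alone took 6.87%, 14.5% and 12.8% of counts in the controls and 20.7%, 17.9% and 17.4% with the guide. How far ribosomal RNA was removed from each library is not given in the sources used here. Their risen and fallen loci numbered 56 and 47 without control 1, 91 and 29 without control 2, and 7 and 23 without control 3, and the risen loci 7, 8 and 9 without Kdm5b guide library 1, 2 and 3. Among these, U1, named after a spliceosomal RNA, had a log2 fold change of -3.52, 7SK one of -1.43 and U4 one of -0.75, while U5, 7SLRNA and BC1_Mm rose by 1.05, 0.98 and 0.27. Outside exons the calls of 7SK, 7SLRNA and BC1_Mm were lost (adjusted p = 0.911, 0.277 and 0.884). The U4, U5 and BC1_Mm calls were also lost without control 3 and without Kdm5b guide library 2 (adjusted p from 0.052 to 0.131, edgeR). Without guide library 1 those of U4 and BC1_Mm were lost (adjusted p = 0.058 and 0.163), and without guide library 3 those of U5 and BC1_Mm (adjusted p = 0.051 and 0.138, edgeR). The BC1_Mm call was further lost without control 2, with library totals or the locus scaling, with no filter, after thinning, outside genes and by limma-voom (adjusted p up to 0.563). Without control 3 or Kdm5b guide library 1, 2 or 3, risen satellite loci numbered 116, 125, 109 and 119.

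With camera the adjusted p was 0.714 for young LINE-1, 0.302 for older LINE-1, 0.583 for SINE B1, 7.0e-09 for SINE B2, B3 and B4, 7.4e-08 for satellites and 0.340 for small RNA repeats. In the same order it gave adjusted p = 0.778, 0.335, 0.569, 0.536, 0.149 and 0.778 with an estimated correlation. Adjusted over the list alone, risen and fallen loci were 96 and 90 for young LINE-1, 151 and 204 for older LINE-1, 616 and 798 for SINE B1, 208 and 459 for SINE B2, B3 and B4, 255 and 32 for satellites, and 17 and 27 for small RNA repeats. Of the 15 repeat lists, 10 passed with the preset correlation, 5 higher and 5 lower, and 0 passed with an estimated correlation. Fry asks whether a list moved at all, not whether it moved more than other loci. It gave adjusted p = 0.027 for VL30, 0.026 for IAP, GLN and SINE B1, 0.0043 for MaLR and 0.0027 for satellites. For ETn with MusD, MuLV, RLTR44 with RLTR45 and older LINE-1 it gave 0.040, 0.048, 0.046 and 0.013. MMERVK10C (0.055), MERVL (0.199), SINE B2 to B4 (0.191), young LINE-1 (0.888) and small RNA repeats (0.988) did not pass. With summed subfamilies in place of loci, 1 list passed. Camera was also run on signed scores from DESeq2 p values, over all loci with such a p. There the calls of MERVL (adjusted p = 0.065), ETn with MusD and MaLR (adjusted p = 0.294 each) were lost. On loci outside genes that of satellites was lost (adjusted p = 0.340, camera).

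As shares of all counts, the 3 libraries of a group lay apart from the other 3 for 12 of 16 repeat groups. The exact two-sided permutation p was 0.1 for each of these, adjusted to 0.133, and 0.1 is the smallest p that 3 against 3 allows. Young LINE-1 elements took 1.07 ± 0.152% of counts in the controls and 0.951 ± 0.0159% with the guide (SD, n = 3 each), which overlapped. Simple and low-complexity repeats took 20.7 ± 4.74% and 26.0 ± 0.786% (SD, n = 3 each).

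Across all repeat names, 207 of 1155 tested subfamilies rose and 168 fell (edgeR), and library totals in place of the scaling gave 142 higher and 269 lower. Several of the largest changes lay mostly in a single host gene exon. MLT1H rose by 3.42 on the log2 scale with 92.9% of its counts at a single locus in an exon of Srxn1, which encodes an antioxidant reductase. X7A_LINE rose by 2.88 with 97.8% of its counts in Txnrd1, and MER89 rose by 3.97 with 51.4% in Oasl1. Outside exons MER89 still rose by 3.07 (adjusted p = 9.0e-05) and MLT1H by 0.83 (adjusted p = 0.0049, edgeR). Outside genes MER89 rose by 2.66 (adjusted p = 3.9e-04, edgeR). Among fallen names, LTR41B had 90.8% of its counts in Dhcr7, a cholesterol synthesis gene, and a log2 fold change of -1.86 that became 0.39 outside exons. RMER17B2 likewise moved from -2.46 to 0.14 outside exons, with 70.3% of its counts in Cp. The mitochondrial tRNA names among these fell, with tRNA-Ser-TCA(m) at -2.85. Sums over loci outside exons called 151 subfamilies, 112 higher and 39 lower, of which 77 were among the 375 calls in the same direction, while 81 of the 375 turned in sign. Sums over loci outside genes called 132, 82 higher and 50 lower, with 68 of the 375 in the same direction and 46 turned in sign. Each of these sums was scaled on its own, which also shifts the values. ORR1A0-int, with 0.22% of its counts in exons, moved from -0.42 to 0.058 outside exons.

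Across single loci, 5231 of 36725 rose and 5485 fell (edgeR). The split was 6639 higher and 4374 lower with the subfamily scaling, 5112 and 2765 by limma-voom, and 3431 and 7410 with no filter on low counts. Among the loci named by the rule, the largest rise was at an Lx8 element in an intron of Sdccag8 (chromosome 1, 176909514 to 176910227), with 0 counts in the controls and 452 with the guide. This was at least 275-fold higher by a floor of 3 counts over the group. Such bounds here hold only if counts are independent. The adjacent MamRep137 element had 0 and 161 counts, at least 98.0-fold higher. A (TTTA)n repeat in an exon of Cxcl2, which encodes a neutrophil chemokine, had 0 and 245 counts, at least 149-fold higher. A (TG)n repeat in an exon of Pax5 had 2 and 164 counts, a ratio of 150 with a 95% counting interval from 40.8 to 1247. The 2 control counts lay in control 1 and may come from a single fragment, so the interval may be too narrow. Among fallen loci, a GA-rich repeat in an intron shared by Banp and Gm20388 (chromosome 8, 121979947 to 121980309) had 878 counts in the controls and 0 with the guide, at least 160-fold lower. Adjacent AT_rich repeats in an exon of Fbn2, which encodes a fibrillin, had 228 and 159 counts in the controls and 0 with the guide, at least 41.6-fold and 29.0-fold lower. Leaving out control 1 raised the count of called loci to 16373, and leaving out control 3 or Kdm5b guide library 1, 2 or 3 gave 5198, 3616, 3358 and 3858. Without Kdm5b guide library 1, 2 or 3 the split leaned up, with 2773 higher and 843 lower, 2637 and 721, and 2991 and 867.

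Called loci clustered by subfamily. MMVL30-int had 189 risen loci of 231 against 32.9 expected (one-sided Fisher's exact test, adjusted p = 1.9e-115), and MMERVK10C-int had 124 of 262 against 37.3 expected (adjusted p = 8.5e-36). MMERGLN_LTR had 149 fallen of 161 against 24.0 expected (adjusted p = 3.3e-105), and the MaLR member MTA_Mm-int had 311 fallen of 734 against 109.6 expected (adjusted p = 4.8e-71). Of 325 subfamilies tested, 26 were enriched among risen and 16 among fallen loci, and a background of loci outside exons gave 24 in all. Loci share reads and hosts, so these p describe the lists of called loci only.

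By position, exonic loci leaned up and intronic loci down. Of 18291 exonic loci 3165 rose and 2211 fell at a median log2 fold change of 0.10. Of 9470 intronic loci 718 rose and 2042 fell at a median of -1.04. Without control 1 the intronic median was -0.41 and the exonic median 0.04. Of 8964 loci outside genes 1348 rose and 1232 fell at a median of -0.19. Exons held 60.5% of risen and 40.3% of fallen loci (odds ratio 2.27, 95% interval 2.10 to 2.45, two-sided Fisher's exact test p = 1.5e-97), and called against uncalled loci gave an odds ratio of 1.02 (0.98 to 1.07, p = 0.377). Leaving out single libraries gave odds ratios between 1.21 and 4.56.

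**Figure D1:**
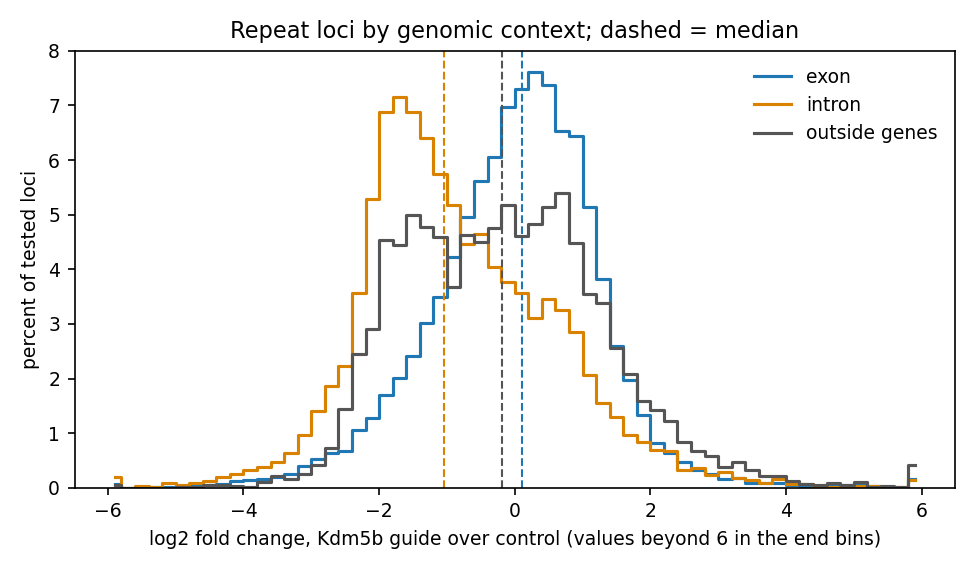
Distribution of the log2 fold change of tested loci in exons, in introns and outside genes, Kdm5b guide against control. The medians were 0.10, -1.04 and -0.19.

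The next comparison read host genes from the repeats inside them, to ask which genes changed with the Kdm5b guide, including those of innate immunity. Genes of the interferon response rose together: of 34 measured members 28 rose, 0 fell and 6 did not pass, with a median log2 fold change of 2.75. Ifit1 (ENSMUSG00000034459.8, chromosome 19, 34640871 to 34650009), an interferon-induced RNA-binding protein gene, rose from 1.16 ± 1.15 to 44.1 ± 5.62 CPM (SD, n = 3 each; log2 fold change 5.35, SE 0.62, adjusted p = 9.2e-04, edgeR). Isg15, a ubiquitin-like modifier gene, rose by 4.15 (SE 0.33, adjusted p = 3.4e-04), and Stat1, a transcription factor of interferon signalling, rose by 2.72 (SE 0.42, adjusted p = 0.0025, edgeR). All 3 were higher in every guide library than in any control. The set test gave adjusted p = 1.2e-16 (camera), and adjusted p = 0.185 with an estimated correlation. Adjusted over the list alone, 29 rose and 0 fell, and in exonic loci alone 23 of 25 rose.

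Antigen presentation genes rose at 5 of 9 measured members, with 0 fallen and 4 that did not pass. H2-Q4 and H2-D1, of the class I histocompatibility family, rose by 2.90 and 1.08, and Calr, a chaperone of the endoplasmic reticulum, rose by 2.41 on the log2 scale. Camera gave adjusted p = 0.0205, and adjusted p = 0.347 with an estimated correlation. Adjusted over the list alone, 6 rose and 1 fell, and scaling by library totals gave 4 higher and 2 lower. Without control 3 or Kdm5b guide library 2 or 3, 3 members rose, and without control 1, 6 rose and 2 fell. Genes of nucleic acid sensing went both ways, with 3 of 15 risen, 2 fallen and 10 that did not pass. Ifih1, a sensor of double-stranded RNA, rose by 3.76 and Tmem173, which encodes STING, fell by 1.37 on the log2 scale, a call lost without Kdm5b guide library 2 (adjusted p = 0.060). The set test gave adjusted p = 0.530 (camera), and adjusted p = 0.559 with an estimated correlation; 3 rose and 2 fell when adjusted over the list alone. Without Kdm5b guide library 2, 1 rose and 0 fell. Ifih1 stands in both this list and the interferon list.

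Genes that silence repeats also went both ways, with 5 of 25 risen, 10 fallen and 10 that did not pass. Dnmt1, the maintenance DNA methyltransferase, fell by 1.84 (SE 0.32, adjusted p = 0.0042, edgeR), and its partner Uhrf1 fell by 1.19. Trim28 and Setdb1, which act together in repeat silencing, had log2 fold changes of -1.44 and -0.91, and both calls were lost without control 3, without Kdm5b guide library 1, 2 or 3 and from intronic loci (adjusted p from 0.053 to 0.175). The Trim28 call was also lost from exonic loci (adjusted p = 0.056) and by limma-voom (adjusted p = 0.091). Zfp809, a zinc finger protein that binds retroviral sequence, rose by 1.67. Camera gave adjusted p = 0.625, and adjusted p = 0.641 with an estimated correlation; 5 rose and 10 fell when adjusted over the list alone. Fallen members numbered 3 without control 3, and 3, 2 and 2 without Kdm5b guide library 1, 2 and 3.

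Cell cycle genes fell at 14 of 17 measured members, with 0 risen and 3 that did not pass, at a median of -2.16. Top2a and Ccnb1, of chromosome segregation and mitotic entry, had log2 fold changes of -2.58 and -2.51. The set test gave adjusted p = 2.2e-05 (camera), and adjusted p = 0.185 with an estimated correlation; 0 rose and 16 fell when adjusted over the list alone. Fallen members numbered 8 without control 3, and 6, 5 and 8 without Kdm5b guide library 1, 2 and 3. In the KDM5 family, 2 of 4 fell, 0 rose and 2 did not pass over all loci, with Kdm5a at -0.62 (adjusted p = 0.0425, and 0.072 with DESeq2 size factors), Kdm5c at -0.31 (adjusted p = 0.294) and Kdm5d at -0.43 (adjusted p = 0.218, edgeR). The KDM5 set gave adjusted p = 0.188 (camera), and adjusted p = 0.406 with an estimated correlation; 2 fell and 0 rose when adjusted over the list alone. From exonic loci all 4 fell at a median of -0.91 (camera adjusted p = 0.033, and adjusted p = 0.255 with an estimated correlation), and over all loci 0 of 4 passed without control 3 or without any single guide library.

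Markers of cell state and of other cell types moved unevenly. Of 6 measured melanocyte lineage genes 1 rose, 1 fell and 4 did not pass: Oca2 rose by 1.16 and Slc24a5 fell by 1.31 on the log2 scale, and both calls were lost without control 3 and without Kdm5b guide library 1 or 2 (adjusted p from 0.074 to 0.122). The Oca2 call was also lost without guide library 3 (adjusted p = 0.051) and with library totals (adjusted p = 0.308), and the Slc24a5 call from intronic loci (adjusted p = 0.192). Of 12 genes of dedifferentiated melanoma 1 rose, 3 fell and 8 did not pass, with Serpine1 at 3.50 and Vim at -2.39. Of 4 fibroblast markers 3 fell and 0 rose, with 1 that did not pass, and 1, 1 and 0 fell without Kdm5b guide library 1, 2 and 3. Of 5 keratinocyte and endothelial markers 2 rose and 0 fell, with 3 that did not pass. Krt10 rose by 1.31, a call lost with library totals, from exonic loci, without control 3 and without Kdm5b guide library 1 or 2 (adjusted p from 0.054 to 0.159), and Krt14, a basal keratinocyte keratin, had 0 counts in the controls and 44 with the guide, at least 35.9-fold higher by a floor of 3 counts over the group. The 1 myeloid and lymphoid marker measured, Adgre1, had a log2 fold change of 0.58 and did not pass.

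In the order melanocyte, dedifferentiated, fibroblast, and keratinocyte with endothelial, the set test gave adjusted p = 0.530, 0.794, 0.069 and 0.141 (camera), and adjusted p = 0.559, 0.797, 0.492 and 0.347 with an estimated correlation. Adjusted over the list alone, risen and fallen members were 1 and 1, 1 and 3, 0 and 3, and 3 and 0 in that order, and 0 and 0 for the myeloid and lymphoid list, for which no set test was run. Scaling by library totals turned the median of the melanocyte list from 0.33 to -0.16 and that of the nucleic acid sensing list from 0.01 to -0.49. Of the gene lists, 3 passed with the preset correlation and 0 with an estimated one, and exonic loci alone gave 5. Fry gave adjusted p = 0.0023 for interferon response, 0.0026 for cell cycle and 0.0044 for antigen presentation. For nucleic acid sensing and the KDM5 family it gave 0.012 each. The dedifferentiated and fibroblast lists gave 0.036 each, and keratinocyte with endothelial markers 0.0044. Repeat silencing (0.265) and melanocyte lineage (0.391) did not pass with fry.

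**Figure D2:**
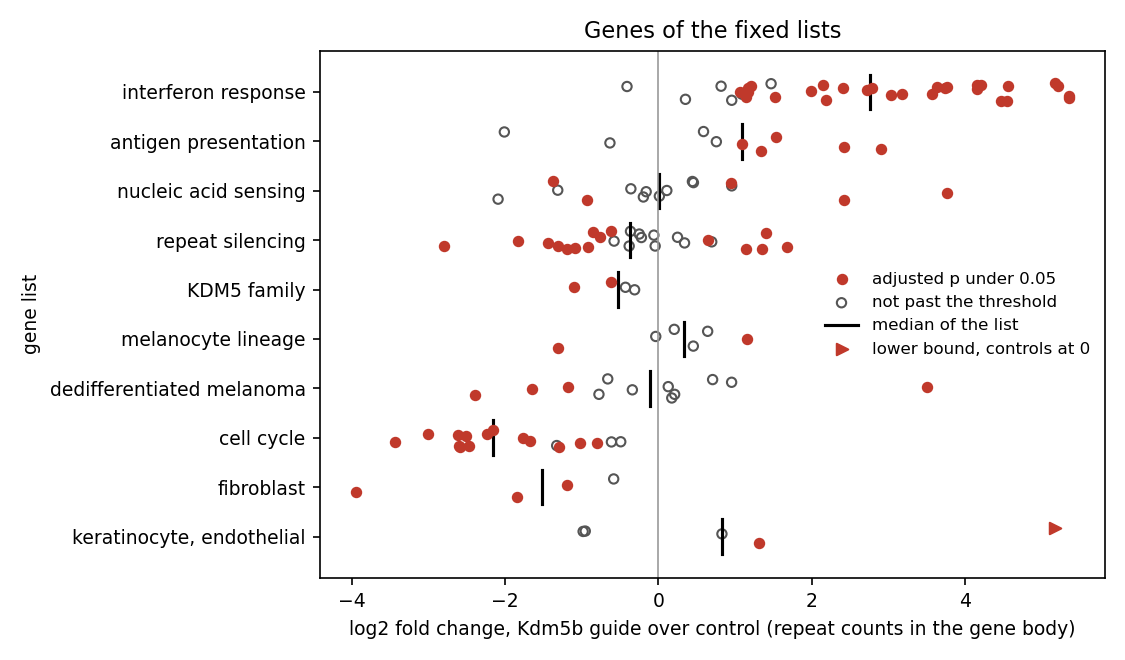
Log2 fold change of each measured member of the fixed gene lists, Kdm5b guide against control, with a point per gene. Interferon response genes had a median of 2.75 and cell cycle genes a median of -2.16, and the triangle marks Krt14, drawn at its lower bound.

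Over all genes, 2006 of 11747 rose and 1979 fell (edgeR). The median log2 fold change of all genes was -0.22 with the scaling used, -0.14 with DESeq2 size factors and -0.69 with library totals, which gave 1131 higher and 3435 lower. Among the genes named by the rule, the largest rises were in Krt16, a stress-induced keratin (ENSMUSG00000053797.10, chromosome 11, 100246091 to 100248902), from 0.361 ± 0.234 to 50.01 ± 6.23 CPM (SD, n = 3 each; log2 fold change 7.19, SE 0.45, adjusted p = 2.0e-04, edgeR), and in the heat shock genes Hspa1b and Hspa1a, at 6.96 and 6.84. Cxcl1, a neutrophil chemokine gene, rose by 5.02. Among the largest falls were genes of the extracellular matrix. Tgfbi had 533 counts in the controls and 3 with the guide, a ratio of 72.6 with a 95% counting interval from 24.7 to 353. Ccn5 had 394 and 3 counts, a ratio of 53.7 with an interval from 18.2 to 261. The intervals for Tgfbi and Ccn5 take counts as independent and may be too narrow. Mgp, Dmp1 and Fbn2 had log2 fold changes of -4.99, -5.09 and -4.58. Leaving out control 3 gave 2205 called genes, leaving out Kdm5b guide library 1, 2 or 3 gave 1985, 2038 and 2064, and intronic loci alone gave 1424. Without guide library 1, 2 or 3 the genes split into 1383 higher and 602 lower, 1396 and 642, and 1416 and 648.

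The authors' deposited table lists 1000 loci, 821 higher and 179 lower with the Kdm5b guide, with a largest adjusted p of 1.0e-06. Of the higher loci in the authors' deposited table, 668 lay in exons, 58 in introns and 95 outside genes. The VL30 list had 32 higher and 1 lower loci in the authors' deposited table. Of its 1000 loci, 999 were tested here by edgeR, and 997 were past the threshold with the same sign as in the authors' deposited table.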

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

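The alternatives of thinning, halved counts, scaling within genomic contexts, exonic loci alone, repeat lists outside genes, the gene list settings, the estimated correlation as a setting, and leaving out libraries for the context and enrichment tests were chosen after the results were seen. With 100 loci changed at each fold size among 36725, simulated 2-fold changes were found at 0% of loci. In the data 29.2% of tested loci were called. Fewer changed loci make an adjusted threshold stricter, so the simulated rate does not give the power in these data.

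Called loci (10716) numbered 10800 with DESeq2 size factors, 11041 with library totals, 10600 by DESeq2, 7877 by limma-voom, 9041 after thinning and 5767 at a mean count of at least 50. Leaving out single libraries gave 3358 to 16373 loci: 16373 without control 1, 5198 without control 3, and 3616, 3358 and 3858 without Kdm5b guide library 1, 2 and 3. Called subfamilies (375) numbered 411 with library totals, 405 by DESeq2 and 323 by limma-voom, and 151 outside exons and 132 outside genes. Leaving out single libraries gave 212 to 483: 219 without control 3, and 212, 225 and 223 without the guide libraries in turn. Called genes (3985) numbered 4566 with library totals, 4118 by DESeq2, 3238 by limma-voom and 1424 from intronic loci. Leaving out single libraries gave 1985 to 5390: 2205 without control 3, and 1985, 2038 and 2064 without the guide libraries in turn. Leaving out a library leaves fewer samples, and why control 1 differs was not tested. Of the calls, DESeq2 also made 8325 of 10716 loci, 356 of 375 subfamilies and 3709 of 3985 genes in the same direction.

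The number of repeat lists that passed (10) was 10 to 11 without single libraries, 7 by DESeq2 (4 higher, 3 lower), 9 on loci outside genes, 1 with subfamily sums and 0 with an estimated correlation. The number of gene lists that passed (3) was 3 to 4 without single libraries, 4 by DESeq2 or with library totals, 5 from exonic loci and 0 with an estimated correlation. Separated shares (12) numbered 9 when small RNA and simple repeats were left out of the totals. Without single libraries they numbered 12 to 14, and the exon odds ratio was 1.21 to 4.56. Enriched subfamilies (42) numbered 26 to 52 without single libraries, 26 of these without Kdm5b guide library 2, and 24 with a background outside exons, where fewer loci were tested.

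With the replicate block, 9154 loci, 308 subfamilies, 3522 genes, 10 repeat lists and 3 gene lists passed, Kdm5b had adjusted p = 0.0526 and 0 of 4 KDM5 genes passed. The numbers do not pair the samples: correlations of same-number libraries over loci were 0.13, -0.07 and 0.16.

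Outside exons the log2 fold change reversed for MamRep38 (-0.16), RMER17B2 (0.14), LTR41B (0.39), Lx3B (-0.30), Lx3C (0.12), MTB (0.0068), ORR1A0-int (0.058) and ORR1B1 (0.081), and outside genes for L1Md_F (-0.14), MT2B (-0.13), ORR1B1 (0.063) and ORR1E (-0.012). From intronic loci it reversed for the genes Cbx1 (-0.29) and Parp14 (-0.23). Over all calls, 81 of 375 subfamilies turned in sign outside exons and 46 outside genes, and of 3985 genes 446 turned from intronic and 38 from exonic loci. Each of these sums was scaled on its own, so a shift in scaling enters the signs along with the loss of exonic loci. ORR1A0-int had 0.22% of its counts in exons, yet moved from -0.42 to 0.058 outside exons and to -0.42 outside genes. MMVL30-int, with 2.12% in exons, moved from 1.92 to 2.46 outside exons. How much each part turned the signs was not tested. Over the other settings of named items, 336 locus results kept direction and side of the threshold and 1 passed no longer; for subfamilies these were 915 and 212, and for genes 1194 and 194.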

Other observations

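The 2 tests on genomic DNA, and those on shared SINE B2 reads, host gene transcription, exonic shift, general stress and zinc finger genes, and the 6 gene groups described next, were chosen after the results were seen. Intervals below for medians, their differences and the variance ratio came from 1000 resamplings of loci or genes. They take loci and genes as independent and hold no spread between libraries, so they do not show how precise an effect is.

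Several stress genes rose with the Kdm5b guide. Of 14 heat shock genes 7 rose, 0 fell and 7 did not pass, with Dnajb1 at 3.67 and Hsp90aa1 at 2.84 on the log2 scale. Of 15 NRF2 targets, which act against oxidants, 8 rose, 1 fell and 6 did not pass, with Srxn1 at 3.94 and Hmox1 at 3.44. Of 15 p53 targets 10 rose, 1 fell and 4 did not pass, with Mdm2 at 2.48 and Cdkn1a, a cell cycle inhibitor gene, at 2.32. Of 8 NF-kB chemokine and related genes 6 rose, 0 fell and 2 did not pass, with Ptgs2 at 3.46.

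Of 22 sterol and fatty acid synthesis genes 18 fell, 0 rose and 4 did not pass (11, 12 and 12 fell without Kdm5b guide library 1, 2 and 3), with Hmgcs1 at -2.92 and Scd2 at -3.49. Of 21 extracellular matrix genes 14 fell (9 and 8 without Kdm5b guide library 2 and 3), 6 did not pass and 1, Thbs1, rose by 2.06. Since these 6 groups were drawn up from genes already seen to change, their counts only describe the data. The groups of libraries also differed in depth and in mitochondrial share.

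VL30 loci rose at a median log2 fold change of 1.64. VL30 loci outside genes lay 2.02 above other loci there (95% interval 1.91 to 2.11). Transcription of host genes would leave them near those loci only if copies shared no reads. How reads that map to several loci were counted is not given. Copies inside genes could thus raise counts outside them, so the gap does not decide on host genes. A single pool of reads shared over all 5 VL30 names would give loci 1 common fold change, but their variance was 4.54 times the mean squared standard error (3.85 to 5.34). Separate pools for each name could spread in the same way, so this says nothing against sharing within a name. After thinning to equal totals the median was 1.59 (1.51 to 1.68). Thinning keeps the expected ratios between scaled libraries, so it could hardly remove a rise and does not decide on depth. A change at many VL30 copies with the Kdm5b guide stays as a hypothesis, and reads shared between near-identical copies limit which copies it concerns: 9 of 28 RLTR6-int copies of nearly equal length had a mean count within 10% of the median copy.

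Interferon response genes rose at 28 of 34 members. A shift of all exonic reads is argued against by their exonic median, which lay 2.59 above that of all genes (95% interval 2.21 to 3.53). Control 1 alone is argued against by the 31 of 35 members that rose without it. A general stress response cannot be told apart: the lower of the heat shock and NRF2 medians lay 1.27 above that of all genes (0.34 to 2.71), but those lists came from genes seen to rise, so the value decides nothing.

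Intronic loci fell at a median of -1.04. Evenly spread genomic DNA is argued against as the whole cause: counts per kb of repeat over 100 kb from genes fell by only 0.12 of the intronic fall (-0.092 to 0.31 over the control libraries), though the share of counts there was higher in each control (0.967%, 0.854% and 0.838%) than in each guide library (0.767%, 0.833% and 0.769%). Most of that intronic fall came from control 1, at 0.69 scaled counts per kb against 0.49 and 0.49 in the other controls and 0.49, 0.45 and 0.43 with the guide, so the ratio says little of controls 2 and 3. Among loci with enough counts to be tested, 480 such loci lay 1.13 above intronic loci (95% interval 0.95 to 1.33). They are only 480 of 271972 loci so far from genes, kept for their counts. That comparison therefore cannot speak on thinly spread genomic DNA. Shared SINE B2 reads are argued against as the whole cause, though not as part of it: without SINE B2, B3 and B4 the intronic median moved from -1.04 to -0.56 and that of loci outside genes from -0.19 to 0.19, a gap of -0.75 (-0.81 to -0.69). Control 1 cannot be told apart as part of the cause: without it the intronic median was -0.41 and the gap to exonic loci -0.45 (-0.48 to -0.42), between the values set for either outcome. Lower transcription of host genes was not settled either, with intronic minus exonic changes of the same genes at -0.51 (-0.55 to -0.48). Introns thus fell more than exons of the same genes. The interval lies outside the range near 0 set for this cause and spans the limit set against it.

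Genes with Zfp names, mostly zinc finger transcription factors, were counted after several had been seen to rise, so the odds ratios describe the lists only. Of 304 tested 107 rose and 21 fell, 35.2% risen against 16.6% of other genes (odds ratio 2.73, 95% interval 2.13 to 3.49, Fisher's exact test p = 1.4e-14). From exonic loci 89 of 276 rose and 27 fell (odds ratio 1.69, 1.29 to 2.21, Fisher's exact test p = 1.2e-04), and with library totals 60 rose and 45 fell. Zfp52 rose by 2.50 and Zfp622 by 2.26 on the log2 scale, both named after their values were seen. Exons of such genes held 48.9% of satellite counts, so the counts are not independent of the satellite list.

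The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 10716 loci, 375 subfamilies and 3985 genes, and the highest of the others called 0 in each table, so 1 of 10 splits was as large.

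The authors' deposited table and the counts gave different sizes at VL30 loci. After the median difference of 0.14 was removed, 893 of 940 loci outside the endogenous retrovirus lists (here with MaLR, RLTR44 and RLTR45 counted as outside) lay within 0.2 and 10 were over 0.5 apart. Of 59 loci in those lists 22 lay within 0.2 and 31 were over 0.5 apart. Of 33 VL30 loci 6 lay within 0.2 and 23 were over 0.5 apart, with a median of 3.37 in the authors' deposited table against 2.03 by edgeR. How reads were counted for the authors' deposited table is not given in the sources used here.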
